A study of Homo sapiens and Drosophila melanogaster with 28 samples.

How the data were processed

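The series mapped proteins on chromatin by ChIP-seq, which sequences DNA bound by an immunoprecipitated protein, in human HCT116 cells (a colon carcinoma line) and in Drosophila S2 cells (an embryo-derived line). It lists 28 samples, of which 9 peak lists were used here: ELL, ICE1, ICE2, ZC3H8 and RNA polymerase II (Pol II) in HCT116, and Ice1 and Pol II in S2. The other 19 samples, which include AFF4, input DNA, the ICE1 and Ice1 knockdowns and RNA-seq, were not analysed here.

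Per the file headers, the authors called peaks with MACS. The ELL, ICE1, ICE2 and ZC3H8 lists were restricted to peaks with an FDR below 5 and a fold enrichment above 5, and the Pol II lists and every S2 list were called at a p limit of 1e-5. The filters therefore differ between the human LEC lists and the human Pol II list. Bowtie 0.12.7, CASAVA 1.8 and MACS, and the builds hg19 and dm3, are named in the submitters' processing notes, without the role of each and without a MACS version. Whether a list was called on 1 library or on pooled libraries is not given in the sources used here. The deposited lists hold 3 columns, the chromosome, start and end of each peak, and no height, score or p for any peak. Sequencing depth is unknown, so the number and width of peaks are the only guide to how much each library yielded.

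Because no peak carries a score, choices planned on scores before the data were examined were replaced by peak width. Strata for matching were 10 width deciles, and the named regions were the widest: 5 per list, 10 for Ice1, the 10 shared regions with the widest ICE1 peaks, and the 5 widest peaks lost or gained after Ell RNAi. Width is not a measure of occupancy, and wide peaks meet other peaks more often by chance. Gene annotation of hg19 and dm3 was not used here, so regions are named by position only and the planned counts of snRNA genes with a peak were left out. Positions are counted from 1, in hg19 for human and dm3 for fly.

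Peaks were counted as overlapping when they shared at least 1 bp. A region was a set of peaks connected by overlaps. Shares carry 95% Wilson intervals and counts carry exact Poisson intervals. These intervals treat peaks as independent and cover counting error only. Chance overlap was described by moving each peak to a random position on its chromosome 1000 times. No allowance was made for unmappable sequence or for kinds of sequence that ChIP peaks favour in general. An overlap above these placements therefore does not by itself show joint binding. Co-occupancy at Pol II peaks was set against the product of the list shares (independent lists) and against 1000 permutations of one factor's marks among Pol II peaks of the same width decile. Ice1-bound fly Pol II peaks were set against 10000 random sets of Pol II peaks without Ice1, matched on width decile. Each human list and the Ell knockdown come from 1 sample, so no difference between conditions has a replicate check and no p-value across peaks was computed. The labels do not say whether the 2 non-targeting Pol II samples came from separate cultures.

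Overlap counts were checked against bedtools 2.31.1 on simulated ZC3H8 and Pol II lists, where both gave 353 overlapping peaks. All 60 regions planted in 4 simulated lists were found. With 100 shared marks planted among Pol II peaks the matched excess was 97.86, and with 0 planted it was 0.15. In 100 simulations of the Ice1-bound comparison with 10 points fewer peaks kept, the mean difference recovered was -9.92 points, against -0.09 with no difference planted. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

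Alternatives planned before the data were examined and run were an overlap of 50% of the shorter peak, peaks within 500 bp counted as shared, and replacing one non-targeting Pol II list by the other. Of 22 such choices, 10 needed a score and 2 needed gene positions, and these were not run. Lists restricted by width, co-occupancy without matching on width, and all results on regions found in 2 of the 3 fly Pol II lists were added after the data were seen.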

Results

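Peak lists were compared for subunits of the little elongation complex (LEC), which the series links to transcription of small nuclear RNA (snRNA) genes, and for Pol II. ELL is an elongation factor, and ICE1, ICE2 and ZC3H8 are the other LEC subunits mapped. In HCT116 the lists held 776 ELL, 763 ICE1, 2882 ICE2 and 9051 ZC3H8 peaks, with median widths of 564.5, 575, 617 and 531 bp. The Pol II list, from cells given a hairpin against GFP as a non-targeting control, held 40229 peaks with a median width of 1111 bp. In S2 the lists held 2200 Ice1 peaks (median width 1838 bp), 7119 and 7781 Pol II peaks in non-targeting replicates 1 and 2 (1292 and 1065 bp), and 7140 Pol II peaks after Ell RNAi (1095 bp). Each group had 1 sample except non-targeting S2 Pol II, which had 2.

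The first comparison asked whether the 4 LEC proteins occupied common sites in HCT116. Their peaks formed 12264 regions, and 62 of these held a peak of all 4 proteins, whereas none of 1000 random placements of the lists gave any. Lists that favour the same kinds of sequence would also exceed uniform placement, so the contrast alone does not show joint binding. The region with the widest ICE1 peak lay on chromosome 12 from 120728337 to 120732241, where the ICE1 peak spanned 3790 bp. Next by ICE1 width came chromosome 1 from 144532295 to 144535899 (ICE1 peak 3048 bp) and from 149221885 to 149225581 (3019 bp). Of the 10 shared regions with the widest ICE1 peaks, 5 were on chromosome 1. A further 2 of these 10 were on chromosome 17, from 56707624 to 56710994 and from 41444101 to 41447161, and the others were on chromosomes 11, 12 and 15. Chromosome 1 held 19 of the 62 shared regions (30.6%, 95% Wilson interval 20.6 to 43.0%), chromosome 19 held 10 and chromosome 17 held 7. By comparison, chromosome 1 held 10.1% (9.54 to 10.6%) of the regions with a single LEC protein. Of the 20 widest peaks in each list, 14 of ELL, 17 of ICE1, 14 of ICE2 and 6 of ZC3H8 lay in shared regions, although these regions held 8.12% of all ELL, 8.52% of ICE1, 2.19% of ICE2 and 0.707% of ZC3H8 peaks. Wide peaks meet other peaks more often by chance, and these counts were not set against peaks of like width. Sites outside the shared regions dominated each list. The widest ELL peak, 10050 bp on chromosome 17 from 57914534 to 57924583, was not in a shared region, and neither was the widest ZC3H8 peak, 3896 bp on chromosome 4 from 31817088 to 31820983.

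More ICE1 peaks met ICE2 than met ELL. ICE2 overlapped 31.2% of ICE1 peaks (28.0 to 34.6%) and ELL overlapped 9.57% (7.68 to 11.9%), against highest shares of 0.917% and 0.393% in random placements. The ICE2 list is longer than the ELL list (2882 against 776 peaks), so these shares do not show that ICE1 met ICE2 in preference to ELL. ZC3H8, the longest list, overlapped 32.2% of ICE1 peaks (29.0 to 35.6%), 23.9% of ICE2 peaks (22.4 to 25.5%) and 22.7% of ELL peaks (19.9 to 25.8%). Of 144 regions with 3 LEC proteins, 105 held ICE1, ICE2 and ZC3H8 without ELL, 30 held ELL, ICE2 and ZC3H8 without ICE1, and 9 lacked either ICE2 or ZC3H8.

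The second comparison set the LEC lists against Pol II. Pol II peaks overlapped 36.3% of ICE1 peaks (33 to 40%), 31.2% of ELL peaks (28.0 to 34.5%), 25.8% of ZC3H8 peaks (24.9 to 26.7%) and 23.3% of ICE2 peaks (21.8 to 24.9%). Randomly placed peaks met Pol II in a median of 3.80 to 3.96% of cases. The share with Pol II rose with the number of LEC proteins, from 21.6% (20.8 to 22.3%) of regions with 1 protein to 40.7% (37.2 to 44.3%) with 2, 65.3% (57.2 to 72.6%) with 3 and 82.3% (71.0 to 89.8%, 51 of 62) with 4. Regions with more proteins were also wider, with medians of 538, 868, 1103 and 1715.5 bp. Among the 10 shared regions with the widest ICE1 peaks, 7 overlapped Pol II. The 3 that did not were those on chromosome 1 from 149221885 to 149225581 and from 16838931 to 16841394, and on chromosome 11 from 62606255 to 62610279. In the other direction, 2723 Pol II peaks (6.77%, 6.53 to 7.02%) overlapped any LEC peak. Pol II was mapped in another ChIP set under another peak filter. Restricting each LEC list to peaks at or above its median width raised the shares to 57.6% for ICE1, 47.4% for ELL, 35.7% for ICE2 and 38.1% for ZC3H8, an alternative chosen after the data were seen.

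**Figure D1:**
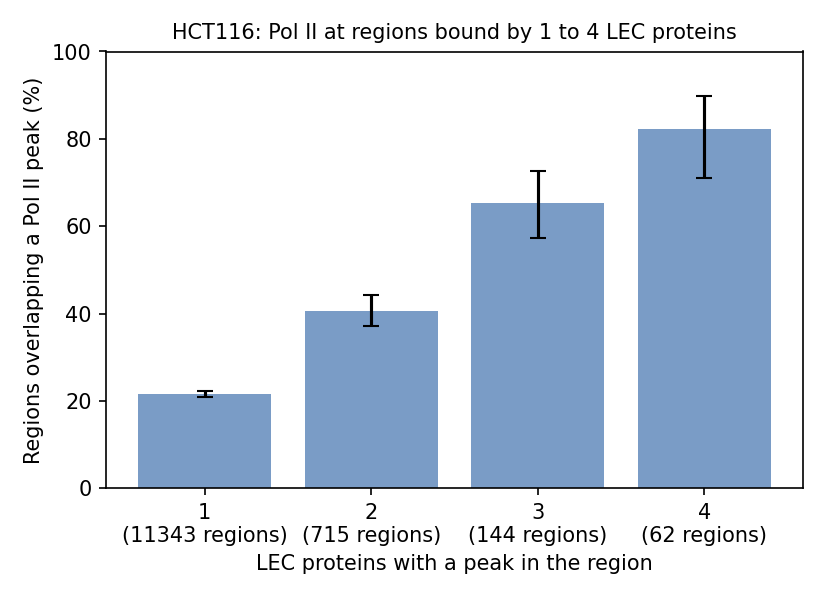
Percentage of HCT116 regions that overlap a Pol II peak (vertical axis) by the number of LEC proteins with a peak in the region (horizontal axis, number of regions in brackets); bars are shares and error bars 95% Wilson intervals. The share rises from 21.6% with 1 protein to 82.3% with 4.

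**Figure D2:**
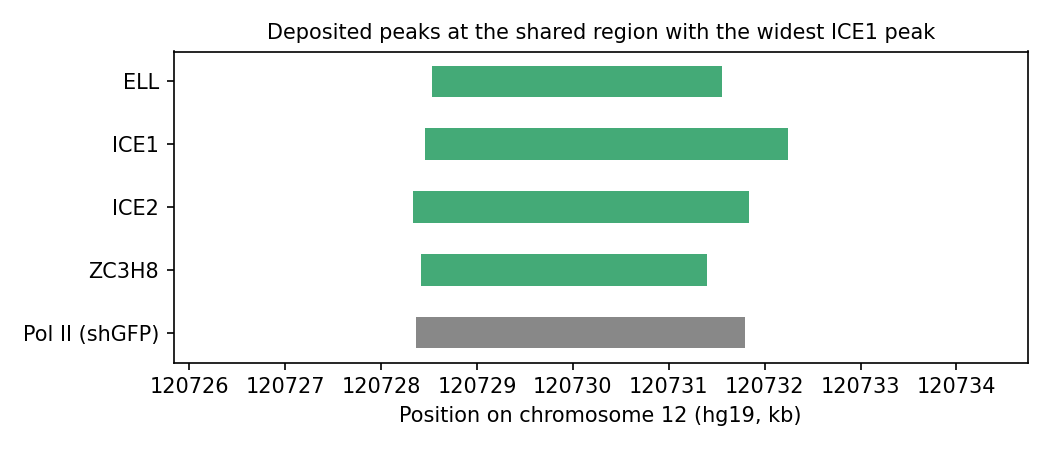
Deposited peaks of the 4 LEC proteins and Pol II (rows) along chromosome 12 in hg19 (horizontal axis, kb) at the shared region with the widest ICE1 peak; each bar is 1 peak drawn to scale. All 5 peaks begin between 120728337 and 120728535.

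The third comparison asked whether LEC proteins met at the same Pol II peaks. All 4 were found at 51 Pol II peaks, against a mean of 0.010 when marks were permuted among Pol II peaks of like width. ICE1 and ICE2 shared 163 Pol II peaks, 25.8 times the matched number (95% Poisson interval 22.0 to 30.0), and ELL and ICE1 shared 63, a ratio of 24.0 (18.5 to 30.8). ELL and ICE2 shared 74, a ratio of 12.4 (9.70 to 15.5). For ZC3H8 the ratio was 7.37 (6.31 to 8.56) with ICE1, 6.28 (5.63 to 6.99) with ICE2 and 5.88 (4.91 to 6.98) with ELL. These ratios do not rank the pairs, because a longer list lowers the highest ratio that a pair can reach. This was 11.8, 12.4 and 10.9 for ZC3H8 with ICE1, ICE2 and ELL, against 43.5 for ICE1 with ICE2, 40.4 for ELL with ICE2 and 92.3 for ELL with ICE1. Of the Pol II peaks with ICE1, 62.5% (56.7 to 68.1%) also held ZC3H8 and 59.3% (53.4 to 64.9%) ICE2, with overlapping intervals. Of those with ELL, 53.7% (47.4 to 59.9%) also held ZC3H8, 30.6% (25.1 to 36.6%) ICE2 and 26.0% (20.9 to 31.9%) ICE1, and of those with ICE2, 50.7% (46.9 to 54.5%) held ZC3H8. Such shares rise by chance with the length of the second list. Without matching on width the ratios were higher, at 38.1 for ELL with ICE1, 9.71 for ELL with ZC3H8 and 11.3 for ICE1 with ZC3H8. Matching covered width only, because the lists hold no score for the strength of a Pol II peak. The ratios therefore do not separate joint binding of LEC proteins from a shared preference for strong Pol II peaks. Each comparison used 1 peak list per protein and has no replicate check.

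**Figure D3:**
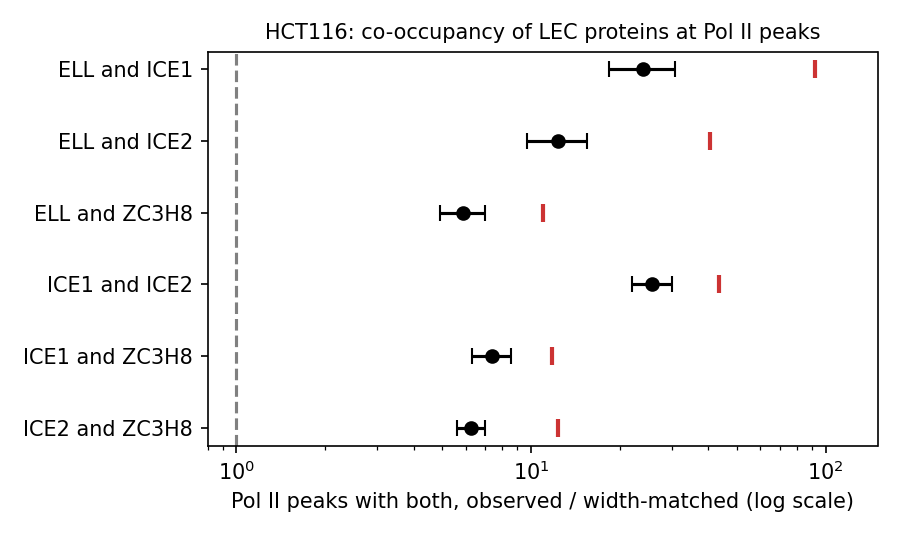
Ratio of observed Pol II peaks holding both proteins to the mean of width-matched permutations (horizontal axis, log scale) for each pair of LEC proteins in HCT116; points are ratios, error bars 95% Poisson intervals, red ticks the highest ratio each pair can reach, and the dashed line marks a ratio of 1. All 6 intervals lie above 1, and the 3 pairs with ZC3H8 lie between 5.88 and 7.37, where at most 10.9 to 12.4 could be reached. The strength of Pol II peaks was not matched.

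In S2 cells, Ice1 peaks were compared with Pol II peaks of the same ChIP set. Pol II overlapped 1107 of 2200 Ice1 peaks (50.3%, 48.2 to 52.4%), against a median of 20.8% and a highest value of 23.1% in random placements. A further view over all 3 Pol II lists left 1015 Ice1 peaks (46.1%, 44.1 to 48.2%) with no Pol II peak. Ice1 peaks without Pol II in the same set were not narrower, with a median of 1894 bp against 1762 bp. The widest Ice1 peaks lay on 3R from 12067768 to 12081585 (13818 bp), on X from 2189523 to 2203029 (13507 bp) and on 3L from 872929 to 885510 (12582 bp). The other 7 of the 10 widest spanned 9123 to 10842 bp, on 2R, 3L, 3R and X. Seen from Pol II, 17.0% (16.2 to 17.9%) of the peaks of non-targeting replicate 1 held an Ice1 peak.

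The Ell knockdown comparison asked which Pol II peaks were still called after Ell RNAi. Of 7781 peaks in non-targeting replicate 2, 6937 (89.2%, 88.4 to 89.8%) were overlapped by a peak after Ell RNAi and 6523 (83.8%, 83.0 to 84.6%) by a peak of non-targeting replicate 1. The knockdown list thus shared more of these peaks than the other control list did, but replicate 2 and the knockdown belong to 1 ChIP set and replicate 1 to another. Starting from replicate 1 the order was reversed: 87.3% (86.5 to 88.0%) of its peaks were found after Ell RNAi and 90.2% (89.5 to 90.8%) in replicate 2. Seen from replicate 1 both lists belong to the other set, so the set was constant there, but the lists differ in length and each comes from 1 sample. Narrow peaks made most of the difference. In the narrowest decile of replicate 2 peaks 60.5% (57.0 to 63.8%) were found after Ell RNAi and 37.2% (33.9 to 40.7%) in replicate 1, while in the widest decile the shares were 96.4% and 97.9%, with overlapping intervals. At peaks matched 1 to 1 the median log2 width ratio to replicate 2 was 0.01 after Ell RNAi (5680 pairs, quartiles -0.0765 and 0.110). In replicate 1 it was also 0.01 (5211 pairs, quartiles -0.0794 and 0.195). Peaks that were split, merged or lost are not covered by these pairs.

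**Figure D4:**
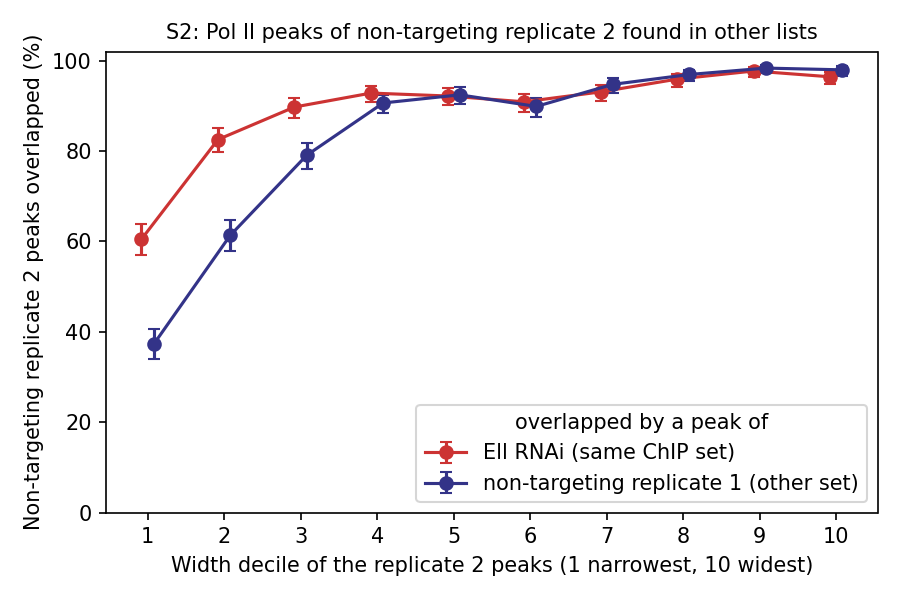
Percentage of S2 Pol II peaks of non-targeting replicate 2 overlapped by a peak of the Ell RNAi list or of non-targeting replicate 1 (vertical axis) by width decile (horizontal axis, 1 narrowest to 10 widest); points are shares and error bars 95% Wilson intervals. The lists differ in the narrowest decile (60.5% and 37.2%) and lie close together in the widest (96.4% and 97.9%).

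The widest replicate 2 peaks with no overlapping peak after Ell RNAi lay on 2R from 6409508 to 6431274 (21767 bp), on 3R from 25603131 to 25622560 (19430 bp), on 2R from 5455066 to 5469051 (13986 bp), on 3L from 3155732 to 3165632 (9901 bp) and on 2R from 4790900 to 4799778 (8879 bp). All of these except the peak on 3R were also in replicate 1. Peaks found after Ell RNAi and in neither control list numbered 337 (4.72%, 4.25 to 5.24%), while 432 regions were in replicate 2 only and 603 in replicate 1 only. The widest of them, on 3L from 884674 to 886917, spanned 2244 bp, and the next, on 2L from 20318766 to 20320897, spanned 2132 bp.

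A last comparison asked whether Pol II peaks that held Ice1 were lost more often after Ell RNAi. Of 1155 Ice1-bound peaks in replicate 2, 92.7% (91.1 to 94.1%) were found after Ell RNAi, against 88.5% (87.7 to 89.3%) of the other 6626. Ice1-bound peaks were wider, and width-matched peaks without Ice1 were found in 92.1% of cases (central 95% of random sets 90.7 to 93.4%), so no difference was detectable after matching. In replicate 1, where no knockdown was made, the same Ice1-bound peaks were found in 93.2% of cases against 89.2% of matched ones (87.7 to 90.6%), a difference of 3.95 points; replicate 1 shares its ChIP set with the Ice1 list. The direction turned with other lists. Among replicate 1 peaks, the share found after Ell RNAi was 85.7% for Ice1-bound and 87.9% for matched peaks, a difference of -2.29 points and outside the central 95% of random sets (86.4 to 89.5%), and in replicate 2, where no knockdown was made, it was 87.6% and 91.2% (89.8 to 92.6%), a difference of -3.64 points. With Ice1 peaks at or above the median width, chosen after the data were seen, bound replicate 2 peaks were found after Ell RNAi in 90.1% of cases against 93.3% of matched ones (91.4 to 95.1%). In replicate 1, without knockdown, these bound peaks went the other way, at 93.3% against 91.2% of matched ones (89.2 to 93.1%). Because replicate 1 shares its ChIP set with the Ice1 list, these 2 differences do not isolate an effect of Ell RNAi.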

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

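Restrictions by peak width, co-occupancy without matching, and counts of regions in 2 of 3 fly lists were chosen after the data were seen. No paired analysis was possible because the results come from peak lists without a fitted test, and only the non-targeting fly Pol II group had 2 lists. Among the choices planned before the data were examined, 10 that needed a score and 2 that needed snRNA gene positions were not run. Of the planned values 15 stayed within the interval of the main value, or within 1.5 times it for counts, 3 moved outside and 2 changed sign. Of the added values 6 stayed, 25 moved outside and 2 changed sign. The 62 shared human regions were 62 with 50% of the shorter peak, 63 within 500 bp and 55 with the wider peaks of each list. Causes of the shifts that follow were not tested.

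With Pol II peaks at or above the median width, the overlap was 26.3% for ELL, 29.5% for ICE1, 17.6% for ICE2 and 21.3% for ZC3H8; with factor peaks so restricted it was 47.4, 57.6, 35.7 and 38.1%. Co-occupancy ratios with wider factor peaks were 32.0 (ELL and ICE1), 16.3 (ELL and ICE2), 7.93 (ELL and ZC3H8), 37.3 (ICE1 and ICE2), 9.53 (ICE1 and ZC3H8) and 7.96 (ICE2 and ZC3H8). Without matching on width they were 38.1, 18.5, 9.71, 35.9, 11.3 and 9.16. All stayed above 1.

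Fly Ice1 overlap with Pol II was 46.3% with 50% of the shorter peak, 48.2% without replicate 1 and 47.6% with wider Ice1 peaks. The share of Pol II peaks kept after Ell RNAi was 94.8% among wider peaks and 87.3% without replicate 2. Its difference from the other control list, 5.32 points, was 6.49 with equal numbers of widest peaks, -0.745 among wider peaks and -2.91 without replicate 2. The Ice1-bound difference, 0.619 points, was -2.29 without replicate 2 and -3.21 with wider Ice1 peaks. Regions found after Ell RNAi and in replicate 1 but not in replicate 2 rose from 71 to 166 with every list at 7119 widest peaks and to 147 at 3559.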

Other observations

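All tests here were chosen after the patterns were seen. In S2 cells Ice1 and Pol II were distributed differently over chromosomes. The X held 8.14% (7.07 to 9.35%) of Ice1 peaks and 15.8% (15.0 to 16.7%) of Pol II peaks of the same ChIP set, while 3R held 28.1% (26.3 to 30.1%) and 24.8% (23.8 to 25.8%). The Ice1 peaks on X met Pol II more often, in 62.0% (54.7 to 68.8%) of cases against 49.3% (47.1 to 51.5%) elsewhere. Regions called after Ell RNAi and in replicate 2 but not in replicate 1 numbered 709, and 28.8% (25.6 to 32.2%) of them were on X, against 17.0% (16.0 to 18.0%) of the 5453 regions in all 3 lists. This was shared by other narrow regions of that ChIP set: X held 25.9% of regions in replicate 2 only and 23.1% of those after Ell RNAi only, but 8.46% of those in replicate 1 only. Median widths were 747 bp for the 709 regions and 1644 bp for those in all 3 lists.

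In HCT116, regions with all 4 LEC proteins were clustered. Of the 62, 18 had another within 100 kb, against a mean of 1.68 and a highest count of 12 in 10000 random sets of LEC regions drawn from the same chromosomes. The sets were not matched on width or on overlap with Pol II, in which shared regions differ from other LEC regions. The densest 5 Mb held 8 of them, on chromosome 1 from 144532295 to 149225581. The 11 shared regions without a Pol II peak lay 749 to 341974 bp from the nearest one, and their median width was 1251 bp against 1807 bp for the shared regions with one.

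Human ELL and ICE1 peaks were frequent on X, at 10.3% (8.36 to 12.6%) and 9.31% (7.44 to 11.6%), against 5.17% of ICE2, 3.31% of ZC3H8 and 2.32% of Pol II peaks. The same mapping trouble spots would place ELL and ICE1 peaks together where both lists call them. On X, 6.25% (2.70 to 13.8%) of ELL peaks overlapped an ICE1 peak, against 9.41% (7.55 to 11.7%) of all ELL peaks. In random placements of all ELL peaks the highest share was 0.387%. Overlapping peaks thus cannot make up most of the ELL peaks on X, but for part of them shared trouble spots stay open. A like number of extra X peaks in each list, whatever its length, stays open because the baseline decides it: above the Pol II share, ELL had 62.0 (45.5 to 81.6) and ZC3H8 90.3 (57.3 to 126) extra X peaks, but above the 5.07% that X takes of chromosome length the values were 40.7 and -159. Background peaks stay open too: X held 13.9% (11 to 17%) of ELL peaks that met no other list against 5.28% (3.32 to 8.29%) of those that did, but for ICE1 the intervals overlapped (11.4%, 8.58 to 15.0%, against 7.25%, 5.07 to 10.3%), ZC3H8 and Pol II, the longest lists to meet, are sparse on X, and Pol II peaks went the other way (2.19% and 4.00%). No biological explanation was tested.

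In S2 cells 262 Pol II regions were in both control lists and missing after Ell RNAi, 3.69 times (2.83 to 4.87) the 71 missing from replicate 2 instead but fewer than the 709 missing from replicate 1. Loss at called Ice1 sites cannot account for all of the 262 missing regions, because 39 of them (14.9%, 11.1 to 19.7%) held an Ice1 peak. The Ice1 list was called at a p limit in another ChIP set, so Ice1 binding below that limit is not covered. For part of the regions loss at Ice1 sites stays open, this share being within the 12.6 to 21.8% of width-matched regions in all 3 lists. A shorter Ell knockdown list stays open: with all lists at 7119 widest peaks the ratio was 1.34 (1.09 to 1.65). This was within the limit of 1.5 set for this explanation, though the interval reaches above it. The regions missing after Ell RNAi went from 262 to 223, and the comparator rose from 71 to 166. A comparator kept low by the longer replicate 2 list would rise in this way. A limit of 5000 bp was chosen after the data were seen. Of 319 replicate 2 peaks above it, 16 had no overlap after Ell RNAi and 9 had none in replicate 1. Of 347 such replicate 1 peaks, 21 had none after Ell RNAi and 11 none in replicate 2. Of the peaks without overlap after Ell RNAi, 5 of the 16 and 3 of the 21 lay within 500 bp of a peak. This held for 1 of the 9 and 1 of the 11 between the control lists. Of 336 such Ell RNAi peaks, 0 had no overlap in replicate 2 and 4 had none in replicate 1. With 1 knockdown list, a gap in peak calling and a loss of Pol II were not separated.

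The third pattern is the 30.6% share of chromosome 1 among regions with all 4 proteins. As the series concerns snRNA genes, binding at those genes is a candidate explanation: in the GRCh38.p14 gene table, chromosome 1 holds 71.4% of 35 Pol II snRNA genes and 10.3% of protein-coding genes. The list was fixed before the data were examined, and its restriction to genes annotated as snRNA was made afterwards to drop pseudogenes. Across 24 chromosomes shared regions correlated with snRNA genes (r = 0.84, permutation p = 0.0065) and about as strongly with protein-coding genes (r = 0.79, permutation p = 1e-05, the smallest the permutations can give), and without chromosome 1 r was 0.23 (permutation p = 0.28) and 0.65 (permutation p = 0.0003). Every chromosome with a listed snRNA gene (1, 2, 11, 12, 15, 17 and 22) held at least 2 shared regions. Chromosomes without one held 0 to 10. Chromosome 19, with 10 shared regions, holds 0 of the listed snRNA genes, while chromosome 17, with 7, holds 1. The snRNA correlation across 24 chromosomes rested largely on chromosome 1, from which the pattern was taken. Outside it the listed genes number only 0 to 3 per chromosome, which leaves r little range to show a relation. Counts per chromosome leave the explanation open, and gene positions in hg19 would be needed to test it.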
